A study of Mus musculus with 2 samples.

How the data were processed

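Small RNA libraries from total RNA of embryonic mouse hearts were analysed from the count files deposited by the authors, 1 per library. Per the labels, the 2 libraries are biological replicates of 1 group, day 15.5 heart, made from separate pools of 78 and 62 embryos. The spread between them is therefore a spread between pools and not between single embryos. Per the text files deposited with the counts, reads were placed on mm10 and the gene counts refer to the GENCODE M4 annotation. The aligner, adapter trimming and counting tool are not given in the sources used here. The deposited counts are whole, unnormalized read counts per miRNA gene in 3 columns, whose layout resembles STAR gene counts with either strand, the strand of the gene and the opposite strand. The second of these, the strand of the gene, was used. The order of the columns was checked on the values, since the counts on the gene's strand far exceeded those on the opposite strand.

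Leading lines of the deposited count files that name no gene stayed out of all totals. Multiply matching reads made up 33.0% of the reads in replicate 1 and 30.1% in replicate 2, and unmapped reads 13.1% and 15.1%. Reads on the strand of no annotated miRNA gene made up 5.11% and 5.07%. These include the reads opposite an annotated miRNA gene, which were 2.97% and 2.55% of all reads. A read that matched several places is in no gene count. miRNA genes with near-identical copies can therefore be undercounted, and their values are uncertain. To mark them, each annotated hairpin was searched for a stretch of 20 bases shared with another annotated miRNA hairpin, which 929 of the 1973 genes and 72 of the 327 detected genes had. Counts are per hairpin, so the arms of a hairpin were not told apart. Gene IDs were matched without version to the GENCODE M21 annotation of the same assembly, which gave symbols, positions and host genes for 1894 of 1973 IDs. A miRNA gene is said to lie in an exon where it overlaps an exon of any annotated transcript of its host, so it can lie in an intron of other transcripts. The 79 unmatched IDs held 1 and 4 counts in replicates 1 and 2.

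Levels were computed as counts per 1000000 of all counts on the gene's strand (CPM), with mean and SD over both libraries and exact binomial (Clopper-Pearson) 95% intervals for shares in a library. Detection required at least 10 counts in both libraries. The reads carried no molecular identifiers in the files used, so intervals and the limit of 3 counts cover counting error only. Totals of 3439539 and 5833156 counts make 1 count worth 0.291 and 0.171 CPM in replicates 1 and 2.

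The libraries were scaled to each other by the trimmed mean of M values (TMM, factors 0.942 and 1.06) in edgeR 4.0.16 under R 4.3.3, which also gave the common dispersion with an intercept alone. Each gene with at least 10 counts summed was compared between the libraries by a two-sided exact conditional binomial test at the scaled library sizes, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test sets the 2 libraries against counting noise alone and compares no conditions. Alternatives were total counts and DESeq2 1.42.0 size factors. A group of 23 lists of miRNAs (213 symbols) was fixed before the data were examined, as were the ratios within pairs, the rule for named genes and the alternatives, except those described as chosen after seeing the data. The lists cover heart, skeletal and smooth muscle, endothelium, mesenchyme, blood cells, epithelium, neural, liver, ciliated, endocrine and sensory cells, pluripotency, and several families or genomic clusters. Of the symbols 18 matched no gene name of the counts and were not used here, among them Mir142 and Mirlet7e.

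List medians of log2(CPM + 0.5) were placed among 10000 random lists of the same size, and list medians of the log2 ratio between replicates among 10000 random lists matched on mean expression in 10 bins. In an alternative chosen after seeing the data, each of 288 clusters (same strand, starts within 50 kb, single genes included) counted once, by its median. The similarity of neighbouring genes was tested with 100000 permutations of detected genes over clusters, where a cluster was a run of genes on the same strand with starts within 10 kb. The smallest p these permutations can give is 1e-05. Symbols without a copy suffix took all copies, and older symbols were used where needed. The rule named the 20 genes with the highest mean CPM, up to 4 leading members per list, the heart muscle list in full, the genes of the pairs, and the 5 genes with the largest called log2 ratio in each direction among those with a mean of at least 100 counts. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

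The procedures were tested on simulated data with known answers. Only the counts for the comparison of replicates and for the coefficient of variation were drawn from the real means and library sizes. For the comparison of replicates, 66.3% of 98 genes changed 1.5-fold and 85.0% of 100 genes changed 3-fold were called with the right sign, against 2.18% of 229 unchanged genes. These counts were simulated with counting noise alone. The rates therefore do not cover calls that arise from a spread between pools or library preparations. A coefficient of variation simulated as 0.1 was recovered as 0.0994 over 336 genes, and one of 0.4 as 0.354 over 330 genes. For the list comparison over 413 genes, 3% of unmoved lists fell in the upper or lower 2.5% of random lists. There the ratios were simulated as independent between genes, so this does not cover lists of neighbouring genes that differ together. For the cluster test on 180 simulated genes in clusters of equal size, the permutation p was 0.726 with no shared level.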

Results

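Mature microRNAs (miRNAs), short RNAs that lower the output of their target mRNAs, were sequenced from the hearts of mouse embryos of strain B6NCrl at embryonic day 15.5. The design holds 1 group with 2 biological replicates, replicate 1 a pool of hearts from 78 embryos and replicate 2 a pool from 62, with both sexes in each pool. Both libraries carried counts for 1973 annotated miRNA genes, each standing for a whole hairpin. Replicate 1 held 7056606 reads, of which 3439539 (48.7%) were counted on the strand of a miRNA gene. Replicate 2 held 11735546 reads, of which 5833156 (49.7%) were so counted. With no second group, the data answer which miRNA genes were counted in the embryonic heart, with what share of the counts, and how far the pools differed. Levels are counts per 1000000 counts on miRNA genes (CPM), and ± gives the SD over both libraries (n = 2). A ratio between different miRNAs is a ratio of counts and need not be one of their amounts in the tissue. In these units 3 counts, the limit that a count of 0 allows, correspond to 0.872 CPM in replicate 1 and 0.514 CPM in replicate 2. Positions are on GRCm38 (mm10).

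A small set of miRNA genes made up most of the counts. Reads that matched several places, 33.0% of reads in replicate 1 and 30.1% in replicate 2, are in no gene count. Genes with near-identical copies, such as Mir1a-1 and Mir133a-1, can therefore rank too low. Mir378a was not among the counted genes. Counts on its strand came to 47438 and 34012 on the CPM scale in replicates 1 and 2, above Mir26b and Mir30e. Whether all are reads of Mir378a was not tested. The ranking below is one of counted genes only. The most abundant was Mir335 (ENSMUSG00000065501.1) at 96967 ± 1311 CPM (n = 2), in an intron of the imprinted gene Mest on chromosome 6, positions 30741299 to 30741396. Mir143 (ENSMUSG00000065445.2), a miRNA of smooth muscle, followed at 85423 ± 4199 CPM on chromosome 18, positions 61649196 to 61649258, outside any annotated gene on its strand. Mir322 (ENSMUSG00000065418.1), of the Mir15 and Mir16 seed family, had 76810 ± 6030 CPM at positions 53054255 to 53054349 of chromosome X. Mir126a (ENSMUSG00000065540.1), the miRNA of the endothelial gene Egfl7, had 73496 ± 8090 CPM and overlaps an exon of that gene on chromosome 2, positions 26591357 to 26591429. Mir99a (ENSMUSG00000065530.1) reached 61179 ± 2081 CPM in an intron of Mir99ahg on chromosome 16, positions 77598936 to 77599000. Mirlet7i (ENSMUSG00000065406.2), on chromosome 10 at positions 122985640 to 122985724, had 58146 ± 1901 CPM. Mirlet7g (ENSMUSG00000065440.1), in an intron of Wdr82 on chromosome 9, positions 106178840 to 106178927, had 56410 ± 68.7 CPM. Mir208b (ENSMUSG00000077928.1), in an intron of the heavy chain myosin gene Myh7 on chromosome 14 (positions 54975700 to 54975776), had 45857 ± 11343 CPM. Mir26b (ENSMUSG00000065468.1) had 31857 ± 2617 CPM in an intron of Ctdsp1 on chromosome 1, positions 74394310 to 74394394. Mir30e (ENSMUSG00000065409.1) had 27773 ± 4568 CPM in an intron of Nfyc on chromosome 4, positions 120772606 to 120772697.

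The 10 most abundant genes held 61.4% ± 3.00 of the counts and the 20 most abundant 78.2% ± 2.34. For the first 10 the share was 63.5% in replicate 1 (exact binomial 95% interval 63.5% to 63.6%) and 59.3% in replicate 2 (59.2% to 59.3%). The other 10 of the 20 ran from Mir351 at 22080 ± 2565 CPM to Mir30d at 11202 ± 1456 CPM. Among them were Mir23a, Mir23b, Mir130a, Mirlet7d, Mir99b, Mir30a, the fibroblast-associated Mir21a (16017 ± 417 CPM, in an exon of Vmp1) and Mir17 (14840 ± 214 CPM), the first member of the Mir17-92 cluster. The hairpins of Mir23a and Mir23b share a stretch of 20 bases, so their counts can fall short of their level. Of these 20 genes, 14 lay inside a host gene on their own strand. At least 10 counts in both libraries were reached by 327 miRNA genes, and 1286 genes had 0 counts in both.

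**Figure D1:**
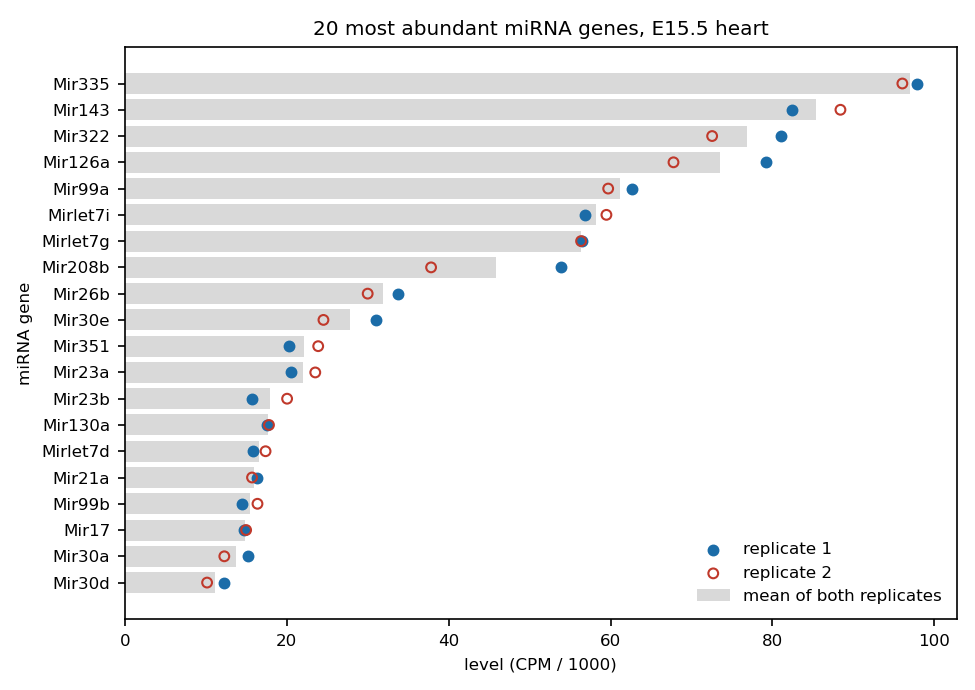
Level of the 20 most abundant counted miRNA genes in CPM divided by 1000 (linear axis). Bars give the mean of both replicates and the points each replicate; Mir335 had the highest mean, 96967 CPM, and Mir208b had the widest gap among the first 10, from 37837 to 53878 CPM.

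The heart muscle miRNAs were led by the miRNAs hosted in myosin genes. Mir208a (ENSMUSG00000065432.1), in an intron of the heavy chain myosin gene Myh6 on chromosome 14 (positions 54949060 to 54949142), had 5886 ± 121 CPM. Mir499 (ENSMUSG00000076312.1), in an intron of Myh7b on chromosome 2 (positions 155622880 to 155622958), had 2160 ± 469 CPM. Mir490, in an intron of the muscarinic receptor gene Chrm2 on chromosome 6 (positions 36421742 to 36421825), had 122 ± 5.96 CPM. Mir208b exceeded Mir208a by 2.94 ± 0.33 on the log2 scale, with a ratio of counts of 9.02 in replicate 1 (exact binomial 95% interval 8.89 to 9.15) and 6.52 in replicate 2 (6.45 to 6.60). Mir499 lay below Mir208a, at a log2 ratio of -1.46 ± 0.29. The heart muscle list as a whole summed to 54028 ± 11926 CPM, or 5.40% ± 1.19 of the counts. Mir1a-1 had 3 and 4 counts in replicates 1 and 2, Mir133a-1 had 5 and 7, and Mir133a-2 had 1 and 4. The hairpins of these genes each share a stretch of 20 bases with another annotated hairpin, and reads that matched several places were given to no gene, so these counts can fall short of the level of the mature miRNAs.

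Among the other cell types of the heart, the smooth muscle list (Mir143 and Mir145a) summed to 86427 ± 4050 CPM and the endothelium list, here Mir126a alone, to 73496 ± 8090 CPM. Within the smooth muscle pair, which lies on chromosome 18 within one cluster, Mir143 exceeded Mir145a (positions 61647825 to 61647894, 1004 ± 149 CPM) by 6.42 ± 0.29 on the log2 scale. The mesenchyme and fibroblast list summed to 23600 ± 1954 CPM. Mir140, which overlaps an annotated exon of Wwp2, had 3901 ± 1514 CPM (2830 in replicate 1 and 4972 in replicate 2). Mir214, which overlaps an annotated exon of Dnm3os, had 2936 ± 849 CPM (2336 and 3536). The log2 ratio of the counts of Mir214 to those of the summed Mir199a genes (148 and 333 counts) was 5.86 ± 0.13, where the Mir199a and Mir199b genes share a stretch of 20 bases, so that this is a ratio of counts and need not be one of levels. The erythroid list reached 1776 ± 963 CPM, and Mir126a exceeded its leading member Mir451a by 6.12 ± 1.12 on the log2 scale. The ratio of counts of Mir126a to Mir451a was 40.1 in replicate 1 and 120 in replicate 2. The leukocyte list reached 693 ± 179 CPM, with the myeloid Mir223 at 403 ± 95.7 CPM. Mir142, another member of this list and of the fixed pair with Mir223, was not analysed here and is not in this sum. On its strand, opposite the gene Mir142b, replicates 1 and 2 had 1585 and 2665 counts per 1000000, more than the whole leukocyte sum.

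miRNAs best known from other tissues were also counted. The epithelium list, which holds the Mir200 family, Mir203 and Mir205, summed to 4059 ± 3165 CPM, led by Mir429 at 1436 ± 1136 CPM. The ciliated cell list summed to 948 ± 235 CPM, the sensory organ list (Mir182, Mir183 and Mir96) to 1167 ± 1056 CPM, the endocrine list to 619 ± 640 CPM and the neural list to 581 ± 314 CPM. The liver list summed to 318 ± 148 CPM, with Mir122, the main hepatocyte miRNA, at 198 ± 157 CPM. The skeletal muscle list had 89.8 ± 20.1 CPM, nearly all of it Mir206 (87.5 ± 20.1 CPM), at a log2 ratio to Mir133b of 5.19 ± 0.30. Mir133b had 8 and 14 counts and shares a stretch of 20 bases with the Mir133a genes, so this too is a ratio of counts and need not be one of levels. The pluripotency list had 866 ± 62.8 CPM, most of it from the Mir302 genes on chromosome 3, with Mir302a at 338 ± 21.3 CPM.

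Of the miRNA families, let-7 had the highest sum. The let-7 family, which accumulates as tissues differentiate, summed to 143005 ± 4026 CPM (14.3% ± 0.403 of the counts), although 5 of its 10 genes share a stretch of 20 bases with another hairpin. The Mir15 and Mir16 family summed to 83640 ± 5940 CPM, most of it Mir322, which exceeded its neighbour Mir503 by 5.49 ± 0.22 on the log2 scale. The Mir30 family had 53011 ± 8089 CPM, the Mir23-27-24 clusters 41890 ± 5268 CPM, and the Mir17-92 cluster with its paralogues, known for driving proliferation, 34343 ± 2336 CPM. In these groups 2 of 6, 5 of 5 and 4 of 15 genes share a stretch of 20 bases with another hairpin. Their counts can therefore fall short of their level. Within the Mir17-92 group the summed Mir92 genes had fewer counts than Mir17, at a log2 ratio of -3.14 ± 0.16, where the Mir92-1 and Mir92-2 genes share a stretch of 20 bases, so that their counts can fall short of their level. The imprinted Dlk1-Dio3 cluster on chromosome 12 summed to 36235 ± 6054 CPM, led by Mir411 (6141 ± 1295 CPM) and Mir487b (5560 ± 356 CPM). The Sfmbt2 intronic cluster had 2804 ± 396 CPM, with 60 of its 61 genes sharing a stretch of 20 bases with another hairpin, so that its counts can fall short of its level. The miRNAs hosted by H19 and Igf2 had 2478 ± 264 CPM, of which Mir483 in an Igf2 intron gave 2369 ± 265 CPM, and the miRNAs of the Hox clusters had 6295 ± 2519 CPM.

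Set against 10000 random lists of the same size from all annotated miRNA genes, 20 of the 23 fixed lists had a median in the upper 2.5% of those lists, as a description of these libraries. The exceptions were skeletal muscle (percentile 87.9), endocrine (95.9) and the Sfmbt2 intronic cluster (49.6). Of the 1973 background genes, 1286 had 0 counts in both libraries, so a list needs no high level to rank high. The neural list, for example, reached percentile 99.9 with a median log2 level of 3.25. Against detected genes alone, 4 lists were in the upper 2.5%, namely heart muscle (98.7), smooth muscle (98.4), endothelium (98.9) and let-7 (99.9), and 0 were in the lower 2.5%. The others of those 20 lists did not stand out among detected genes. This comparison leaves out undetected members. Without Mir1a-1, Mir133a-1 and Mir133a-2 the heart muscle list fell from 7 genes to 4, and its median log2 level rose from 6.94 to 11.8. The endothelium list is 1 gene and the smooth muscle list 2.

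The library of replicate 2 held more of the miRNAs of the epithelium and Hox lists than that of replicate 1. In the epithelium list all 7 genes were higher in replicate 2, 7 passing the test and 7 when adjusted over the list alone, with a median log2 ratio of replicate 1 to replicate 2 of -1.65. Its sum was 1821 CPM in replicate 1 and 6297 CPM in replicate 2. Mir200c, on chromosome 6 (positions 124718322 to 124718390), had 357 and 1672 CPM in replicates 1 and 2. Mir205, a miRNA of stratified epithelium on chromosome 1 (positions 193507463 to 193507530), had 148 and 852 CPM. In the sensory organ list 3 of 3 genes passed (3 adjusted over the list alone), with a median of -1.92, but they form a single genomic cluster. With each cluster counted once, an alternative chosen after seeing the data, the percentile was 8.87, inside the central range of random lists. Mir182 (chromosome 6, positions 30165918 to 30165992) had 202 and 865 CPM. In the neural list 8 of 9 genes were higher in replicate 2 and 3 passed (3 adjusted over the list alone), with a median of -1.13. Of these 3, Mir128-1 and Mir128-2 share a stretch of 20 bases, and with members of at least 100 counts the median was -0.61 (percentile 3.69 of matched random lists). Mir137, a neuronal miRNA on chromosome 3 (positions 118433857 to 118433929), had 44.2 and 234 CPM. In the Hox list 5 of 5 passed (5 adjusted over the list alone), with a median of -0.82 and Mir10a (chromosome 11, positions 96317165 to 96317274) at 2968 and 5452 CPM. In the Dlk1-Dio3 list 32 of 41 genes were higher in replicate 2, of which 19 passed, and 3 genes passed in the other direction (19 and 3 adjusted over the list alone). The median was -0.16, inside the central range of random lists with clusters counted once (28).

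The heart muscle list leaned toward replicate 1. In the heart muscle list 5 of 5 tested genes were higher in replicate 1 and 3 passed (3 adjusted over the list alone), with a median log2 ratio of 0.49. That median is the value of Mir133a-1, with 5 and 7 counts, and with members of at least 100 counts it was 0.42 (percentile 99 of matched random lists). Mir490 (118 and 126 CPM) was not higher in replicate 1 by total counts, but was so after TMM scaling. Mir208b had 53878 CPM in replicate 1 and 37837 CPM in replicate 2, and Mir499 had 2492 and 1829 CPM. In the Mir30 family 6 of 6 genes were higher in replicate 1 and 5 passed (5 adjusted over the list alone), with a median of 0.46, which left the upper 2.5% of random lists with clusters counted once (96.5). The Mir15 and Mir16 family had a median of 0.27, with 4 genes higher in replicate 1 and 1 higher in replicate 2 passing (4 and 1 adjusted over the list alone), and left the upper 2.5% in the same way (92.4). The pluripotency list had a median of 0.30, with 2 of 8 genes passing (2 adjusted over the list alone), and did so too (77.0). The called gene with the largest difference toward replicate 1 was the erythroid Mir451a, on chromosome 11 (positions 78073170 to 78073241), at 1975 CPM in replicate 1 and 564 CPM in replicate 2, a log2 ratio of 1.98. Its neighbour Mir144 had 401 and 422 CPM, so that the log2 ratio of Mir144 to Mir451a was -2.30 in replicate 1 and -0.42 in replicate 2 (-1.36 ± 1.33). The next genes higher in replicate 1, among those with a mean of at least 100 counts, were Mir378d (0.99), Mir215 (0.86), Mir194-1 (0.79) and Mir378c (0.79). With the same minimum, the largest differences toward replicate 2 were those of Mir375 (-2.65), a miRNA of endocrine cells on chromosome 1 (positions 74900658 to 74900721), Mir20b (-2.51), Mir205 (-2.35), Mir363 (-2.30) and Mir137 (-2.23).

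**Figure D2:**
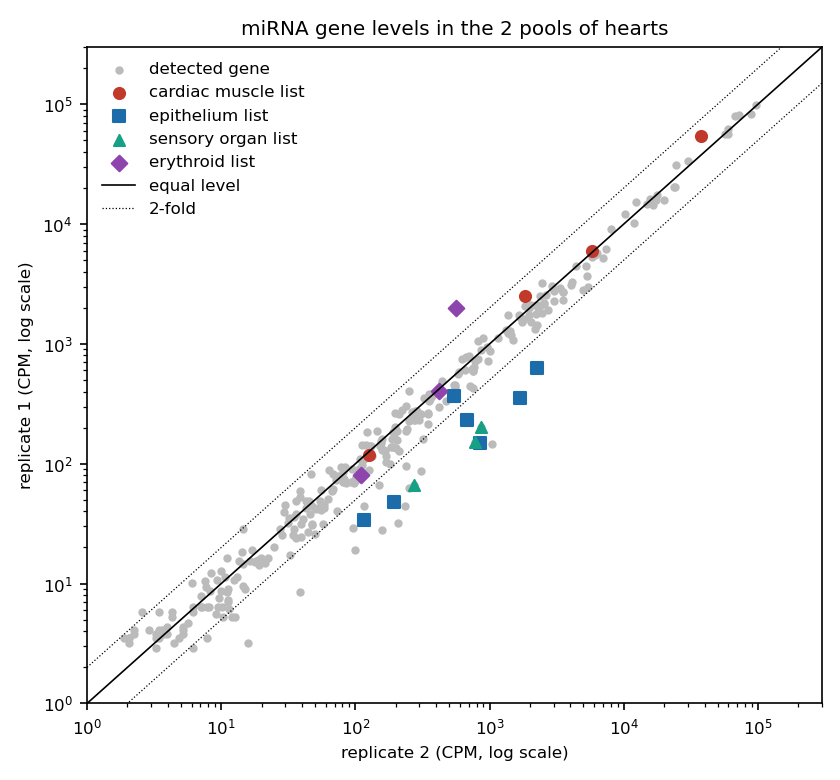
Level of each detected miRNA gene in replicate 1 against replicate 2, both in CPM on log axes, with the line of equal level and dotted lines at 2-fold. Coloured symbols mark 4 fixed lists. All 3 sensory organ genes and 6 of 7 epithelium genes lie beyond 2-fold toward replicate 2, and Mir451a of the erythroid list lies beyond it toward replicate 1.

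Against expression-matched random lists, 9 of the 23 lists lay in the upper or lower 2.5%. The percentiles were 0.13 for epithelium, 0.60 for sensory organ, 0.125 for neural, 0.44 for Hox and 1.37 for Dlk1-Dio3, and 99.4 for heart muscle, 99.8 for Mir30, 98.3 for Mir15 and Mir16 and 97.7 for pluripotency. The other 14 ranged from 6.32 for endocrine to 88.9 for endothelium. These lists draw genes singly, while neighbouring genes differed between the libraries together, so the percentiles are too extreme for lists made of clusters. With each genomic cluster counted once, an alternative chosen after seeing the data, heart muscle (98.0), epithelium (0.19), neural (0.14) and Hox (1.89) stayed outside. Endocrine (1.57) came to lie outside too. The heart muscle value rests on 4 clusters with a median of 0.47, among them Mir133a-1 alone with 5 and 7 counts. The other 5 of the 9 lists did not lie outside. With members of at least 100 counts pluripotency (0.30, 96.6) and Dlk1-Dio3 (-0.16, 2.70) did not either, nor did neural. These percentiles describe 2 libraries and test no condition.

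**Figure D3:**
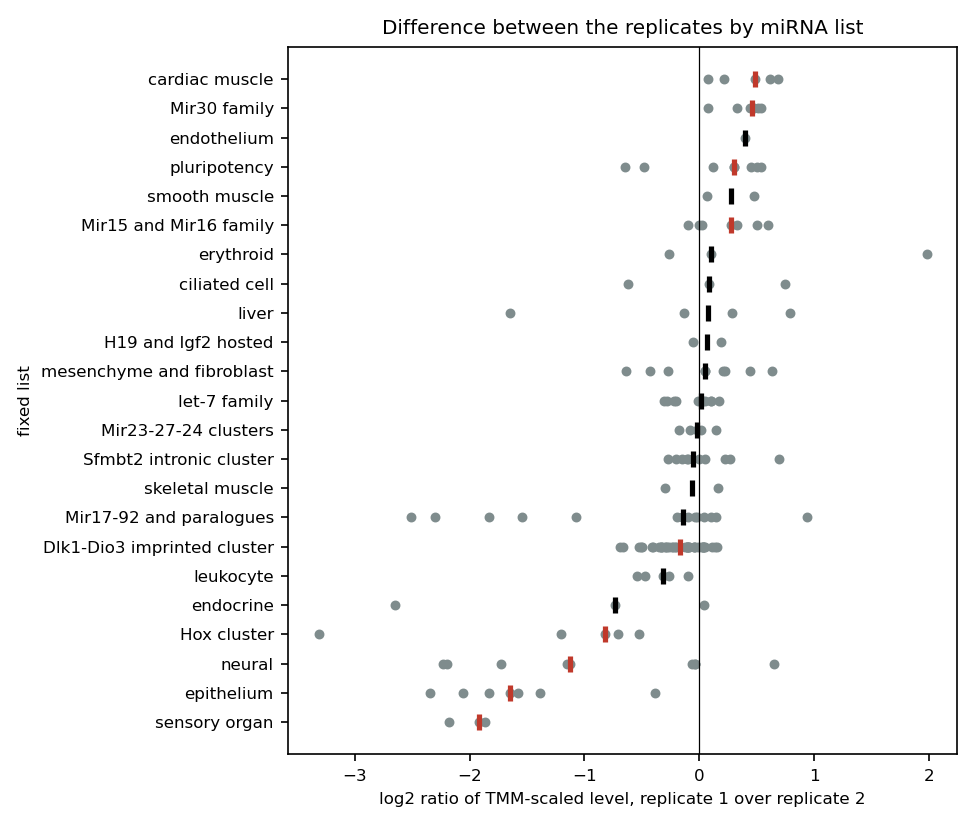
Log2 ratio of the level scaled by the trimmed mean of M values, replicate 1 over replicate 2, for each member of the 23 fixed lists (points) and the median of each list (vertical tick). Red ticks mark the 9 lists in the upper or lower 2.5% of matched random lists of single genes and black ticks the others. Medians run from -1.92 for sensory organ to 0.49 for cardiac muscle.

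The libraries were also compared gene by gene with counting noise, which leaves out the spread between pools and between library preparations. Of 413 genes with at least 10 counts summed, 191 differed in an exact conditional binomial test with Benjamini-Hochberg adjustment, 89 higher in replicate 1 and 102 in replicate 2. A chi-square over the same genes was 77187 on 412 degrees of freedom, so the libraries were not one library deposited again. Scaling by total counts moved the median log2 ratio of the tested genes from -0.035 to -0.21 and gave 47 and 155 calls, and DESeq2 size factors gave 102 and 85, so the split depends on the scaling. Differences of at least 2-fold lay mostly toward replicate 2 under each scaling, with 3 genes higher in replicate 1 and 32 in replicate 2 (1 and 37 with total counts, 4 and 30 with DESeq2 size factors). Most genes differed little, since 262 of the 327 detected genes (80.1%) lay within 1.5-fold. Across detected genes, which are not independent replicates, Pearson's r of the log2 levels was 0.984 and Spearman's rho 0.980. The biological coefficient of variation estimated by edgeR was 0.288. It rests on 1 residual degree of freedom per gene, and with 1 library per pool a difference between pools cannot be separated from one of preparation.

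Neighbouring miRNA genes were compared in level as well. In 41 genomic clusters of 147 detected genes, the mean SD of log2 CPM within a cluster was 2.55, against 2.96 for genes shuffled over clusters (one-sided permutation test, p = 0.0597), which did not pass the threshold of 0.05. Clusters drawn with gaps of at most 3 kb (2.29, permutation p = 0.00598) or 50 kb (2.43, permutation p = 0.0183) did pass. Single clusters spanned wide ranges, as in the ratio of Mir143 to Mir145a of 74.3 in replicate 1 and 98.4 in replicate 2.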

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

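Counts on the strand opposite to the annotated gene entered no main result, only the alternative that counts either strand, and they lay far above the limit of 3 counts that a count of 0 allows. Their total was 209241 in replicate 1 and 299184 in replicate 2. At 9 genes the opposite strand held at least 1000 counts in both libraries, and these genes carried 99.6% of the total in each. In the newer annotation of the same assembly each of them overlaps a miRNA gene on the other strand that is not among the counted genes.

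The largest signal was at Gm25301 on chromosome 18, positions 61397813 to 61397925, with 163166 opposite-strand counts in replicate 1 and 198395 in replicate 2, where Mir378a lies at positions 61397835 to 61397900 on the other strand. Per 1000000 counts on miRNA genes this is 47438 and 34012, within the range of the 10 most abundant genes. Gm25927, opposite Mirlet7e, had 14998 and 30344 such counts. Gm24321, opposite Mir409, had 7792 and 19360. Gm24083, opposite Mir191, had 7285 and 14659. Mir142b, opposite the leukocyte miRNA Mir142, had 5452 and 15543. Gm25252, opposite Mir376a, had 4014 and 8602. Mir299b, opposite Mir299a, had 3034 and 5830. Mir497b, opposite Mir497, had 1462 and 2834. Gm25750, opposite Mir380, had 1243 and 2304. On their own strand these genes had at most 10 counts in a library. The opposite-strand counts thus lie where reads of the uncounted miRNA genes would fall. Whether all of them are reads of those genes was not tested.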

How the results depend on the processing

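The alternatives were fixed beforehand except for 3 chosen after seeing the data: lists without genes that share a 20-base stretch with a copy, calls of at least 2-fold, and lists with each genomic cluster counted once. The number of genes differing between replicates ran from 180 to 202 with total counts, DESeq2 size factors, either strand and no filter, and each list percentile of the level kept its side with either library alone. Of the alternative values for results that answer a comparison, 35 changed side of the threshold or moved by more than 1.5 times (counts of genes) or 1 SD, and follow here. Of those for single genes and list sums, 53 moved by more than 1 SD. With n = 2, leaving out a library cannot move a mean by 1 SD, so that step is given as ranges below. The cause was not tested unless stated. With counts on either strand the mean level of Mir335 was 91818 CPM, since the total grows by the opposite-strand counts. With a minimum of 1 count 531 genes were detected and with 50 counts 264, as such limits must give. With detected genes as background, which leaves out undetected members, list percentiles were 45.6 for leukocyte, 19.8 for neural, 17.6 for liver and 7.48 for pluripotency, below the middle, as were endocrine (14.3, from 95.9) and skeletal muscle (40.7, from 87.9), which were not called before. They were 80.1 for mesenchyme, 73.3 for erythroid, 83.5 for epithelium, 70.1 for ciliated cell, 74.5 for sensory organ, 68.7 for Mir17-92, 81.1 for Dlk1-Dio3, 73.8 for H19 and Igf2, 96.5 for Mir15 and Mir16, 96.1 for Mir30, 92.2 for Mir23-27-24 and 84.3 for Hox. With genes that have copies left out of both lists and background they were 97.465 for erythroid, 96.5 for leukocyte, 96.2 for neural, 93.5 for liver, 92.9 for ciliated cell and 95.8 for pluripotency, and the Mir23-27-24 list had no member left. With members of at least 100 counts the median log2 ratio between replicates was -0.61 for neural, 0.30 for pluripotency and -0.16 for Dlk1-Dio3, none of them in the upper or lower 2.5%. With each cluster counted once it was -1.92 for sensory organ, 0.14 for pluripotency, -0.25 for Dlk1-Dio3, 0.26 for Mir15 and Mir16 and 0.42 for Mir30, no longer there, and -0.74 for endocrine, now there. The within-cluster SD was 2.29 with 3 kb and 2.43 with 50 kb, past the threshold, and 2.46 with a pseudocount of 5 CPM (permutation p = 0.127). Total counts change no list percentile of the ratio, since they move each gene by one amount, but they turn the sign of the medians for mesenchyme, erythroid, liver, ciliated cell, let-7 and H19 and Igf2, which were not called.

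Leaving out each replicate in turn moved 7 of the 23 list sums and 28 of the 88 named genes over a range of more than 1.5-fold. The sums ranged from 166 to 1071 CPM for endocrine, 421 to 1914 for sensory organ, 1821 to 6297 for epithelium, 1095 to 2457 for erythroid, 359 to 804 for neural, 213 to 423 for liver and 4514 to 8076 for Hox. Mir122 ranged from 87.2 to 309 CPM and Mir429 from 634 to 2239. The same step gave 96040 to 97894 CPM for Mir335, 327 to 384 detected genes, 59.3% to 63.5% in the 10 most abundant genes, and a within-cluster SD of 2.55 in each case. The log2 ratio of Mir144 to Mir451a ranged from -2.30 to -0.42, and that of Mir126a to Mir451a from 5.33 to 6.91. Comparisons between replicates and the coefficient of variation need both libraries, so leaving one out gave no value. No paired analysis was possible because there is 1 group. Depth limits the genes near 3 counts, and the coefficient of variation was 0.285 with DESeq2 size factors, 0.302 without a filter and 0.284 at 100 counts or more.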

Other observations

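The tests in this part were all chosen after the values had been seen. A cluster on chromosome X, positions 52741693 to 52742567, that holds Mir363, Mir92-2, Mir20b, Mir18b and Mir106a, a paralogue of the Mir17-92 cluster, had a median log2 ratio of replicate 1 to replicate 2 of -1.83, while the Mir17-92 cluster itself on chromosome 14 had -0.070. Mir106a had 62.5 CPM in replicate 1 and 251 CPM in replicate 2. Other clusters moved in step as well, such as Mir182, Mir96 and Mir183 on chromosome 6 (median -1.92) and Mir141 with Mir200c on the same chromosome (-1.94). Toward replicate 1 lay Mir194-1 with Mir215 on chromosome 1 (0.82).

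These clusters led to a test of whether neighbouring miRNA genes differ between the pools together. The mean SD of the log2 ratio within 41 clusters was 0.23, against 0.48 for genes shuffled over clusters (permutation test, p = 1e-05, the smallest the permutations can give). Without genes that share a 20-base stretch with a copy, it was 0.26 against 0.51 (25 clusters, 96 genes, permutation p = 4e-05). This is consistent with miRNAs of one transcription unit varying together between pools, as a hypothesis found and tested on the same data. Several clusters went against it, among them Mir144 and Mir451a on chromosome 11 (0.10 and 1.98), Mir292 to Mir294 (-0.48 to 0.54), Mir770 to Mir434 (-0.67 to 0.14), Mir15b with Mir16-2 (-0.094 to 0.60) and Mir34c with Mir34b (0.082 to 0.74).

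The epithelium list was higher in replicate 2, at a median log2 ratio of -1.65. GC content of the hairpins is argued against as the whole cause, since the median was -1.48 after the GC trend over all tested genes was removed. GC content of the mature miRNAs was not tested. RNA of other organs in replicate 2 stays open: over 18 members of the neural, liver, ciliated cell and skeletal muscle lists the median was -0.095 (percentile 38.7 of matched random lists), with members going both ways, Mir137 (-2.23) and Mir122 (-1.65) among those higher in replicate 2. Beside these technical explanations no biological explanation was tested, since the design has 1 group. A difference in library preparation was not tested and stays open.

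Mir451a was higher in replicate 1 by 1.98 on the log2 scale. A greater share of erythroid cells in replicate 1 that raised Mir144 as much as Mir451a is argued against by Mir144. It lies beside Mir451a on the same strand and had a log2 ratio of 0.0998 (counting interval 0.0046 to 0.195). That interval leaves out the spread between pools and library preparations, so the argument is weaker than its width implies. Mir144 cannot decide on a greater share of erythroid cells that raised Mir451a alone. Mir486, also of the erythroid list, had -0.27. No other explanation was tested, and a difference in library preparation stays open.

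Mir1a-1, Mir133a-1 and Mir133a-2, whose mature miRNAs are among the best known of heart muscle, had at most 7 counts in a library. A candidate explanation is that reads matching identical copies were left out. Over the fixed lists, without the Sfmbt2 intronic cluster, the 52 members that share a 20-base stretch with another hairpin had a lower median log2 level than the 123 others (5.57 against 8.05, a difference of -2.48, one-sided permutation test, p = 2e-05). Sharing differed between the lists, with 9 of 13 neural, 5 of 5 Mir23-27-24 and 0 of 2 smooth muscle genes. The medians pool lists of unlike level and members of 1 family, so the difference cannot be assigned to left-out reads alone. Lower expression of Mir1a-1, Mir133a-1 and Mir133a-2 cannot be judged from the counts.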
